A study of Mus musculus with 24 samples.

How the data were processed

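RNA was taken from the dissected hippocampus, cortex and cerebellum of wild-type mice after olfactory bulbectomy, the surgical removal of the olfactory bulbs, or after a sham operation. Per the labels' protocols, only RNA with an integrity number of at least 8 was used, directional polyA libraries were prepared with the NEBNext Ultra II kit, and single-end reads were sequenced on an Illumina NextSeq. The 24 libraries fell into 6 groups: 4 bulbectomy and 5 sham libraries of hippocampus, 3 and 5 of cortex, and 2 and 5 of cerebellum. Tissue and treatment came from the labels of each library and the replicate number from its title. Cortex bulbectomy 3 and cerebellum bulbectomy 3 and 4 were not analysed here.

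The deposited files hold raw counts, whole reads per Ensembl gene, 1 file per library. Per the submitters' processing notes the authors used Trimmomatic, STAR and featureCounts with the mm10 build. Versions, annotation release, strand setting and the handling of reads that match several places are not given in the sources used here. Each file lists 55487 gene identifiers and 12 totals of read assignment. In each of the 24 files the gene values sum to the assigned total. The reads of the other totals were kept out of library sizes and tests. Shares were taken over assigned reads, reads overlapping no gene and reads matching more than 1 gene, without the remaining totals. Reads overlapping no gene made up 2.62% to 9.22% of these and reads matching more than 1 gene 3.92% to 5.08%, together 6.61% to 13.26%.

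GENCODE M21 on GRCm38 (mm10) holds 55227 of the identifiers and gave coordinates (counted from 1), exon lengths and GC content. A symbol was found for 55141. Because the strand setting is not given, genes whose exons overlap another gene are treated as uncertain. Of the 112 genes named by rule, 16 share exon bases with a gene on the same strand and 28 with a gene on the opposite strand.

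The tests below were chosen before the data were examined, except where the text says otherwise. Within each tissue, genes passing edgeR's filterByExpr were scaled with TMM and tested with edgeR's quasi-likelihood test (estimateDisp, robust glmQLFit, glmQLFTest, edgeR 4.0.16, R 4.3.3), bulbectomy against sham. P-values are two-sided, adjusted by the Benjamini-Hochberg method over all genes tested in the tissue, and a gene was called at an adjusted p under 0.05 with no fold threshold. Fold changes are bulbectomy minus sham on the log2 scale with standard errors from the same fit, and levels are CPM, the counts of a gene relative to the scaled library total. Differences of the bulbectomy effect between tissues were tested as interaction contrasts in a fit of all 24 libraries with 6 group means. Overlaps of called genes were tested with Fisher's exact test, one-sided, over the genes tested in both tissues.

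A set of 50 gene lists of brain cell types, brain regions and pathways was fixed beforehand; 967 of their 975 symbols were found. Lists with at least 4 measured members were tested with limma's camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a tissue. No list was called in any tissue with an estimated correlation, and fry, which asks only whether a list's genes move one way on balance, called 1. In simulated counts a list raised 1.5-fold was called at the preset correlation in all 3 tissues, with 1 unchanged list called besides it in the hippocampus. With an estimated correlation it was called in the cortex alone and no unchanged list was called. A p that misses the threshold there therefore excludes no change. Genes were simulated independently of each other, while the real hippocampus lists had a median estimated correlation of 0.123. The simulation therefore cannot show how often the preset correlation calls unchanged lists in these data. Other splits of the real libraries called a median of 11 lists in hippocampus, 10 in cortex and 9.5 in cerebellum. For each called list the members called over all genes and those passing when adjusted over the list alone were counted.

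The genes to be named followed a fixed rule. In each tissue they were the 10 genes of smallest p among those called higher and the 10 among those called lower, without predicted names, or all where fewer passed. Where fewer than 5 passed, the 5 of smallest p were named as values. Up to 4 members of smallest p of each called list were added, and a panel of genes linked to Alzheimer's disease, depression and plasticity was followed in every tissue. The values of 2 genes taken by this rule are not reported here.

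The alternatives were DESeq2 1.42.0, limma voom with sample weights, RLE and upper-quartile scaling, other filters on low counts, a non-robust fit, a fold threshold of 1.2, the replicate number as a block, each library left out in turn, and all libraries in 1 fit. Chosen after the data were seen were thinning the deepest library, removing a trend over exon length and GC content, and leaving out pairs of libraries. The steps were tested on simulated counts made from the real gene means. At a 2-fold change the share of changed genes called was 34.3% in hippocampus (13687 genes tested), 35.8% in cortex (14687) and 0% in cerebellum (14918), and at 4-fold 90.9%, 89.4% and 19.7%. False calls were 7 of 95, 11 of 95 and 1 of 14 calls. For differences of effects they were 1 of 80 for hippocampus against cortex, 22 of 103 for hippocampus against cerebellum and 12 of 70 for cortex against cerebellum, and the share of changed genes called was 6.8%, 6.8% and 1.5% at 2-fold and 51.9%, 52.7% and 44.1% at 4-fold. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

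No library pair of a group held identical files: over the 40 pairs, the chi-square statistic per degree of freedom, over genes with at least 20 reads in the pair, was 11.8 to 387. The labels do not say whether libraries of 1 group come from separate animals or whether the same number in different tissues marks 1 animal. P-values therefore measure the spread between these libraries. No batch, date or lane is labelled, so a batch difference between bulbectomy and sham libraries cannot be told apart from the operation.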

Results

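Gene expression was measured by RNA-seq in the hippocampus, cortex and cerebellum of wild-type mice whose olfactory bulbs had been removed and of sham-operated mice. The question posed by the design is how the loss of the bulbs alters expression in each brain region, and the series title relates it to Alzheimer's disease and depression. The hippocampus was represented by 4 bulbectomy and 5 sham libraries, the cortex by 3 and 5, and the cerebellum by 2 and 5. Hippocampus sham 4 was the deepest library, with 138963332 reads assigned to genes, and hippocampus sham 1 the shallowest, with 3255661. The other hippocampus libraries held 8145624 to 9608811 assigned reads. The cortex libraries held 10073878 to 17052728 and the cerebellum libraries 10400540 to 20230673. Reads of mitochondrial genes took 2.53% to 13.28% of the assigned reads, and the 10 most abundant genes 8.39% to 27.56%.

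Marker levels set the cerebellum libraries apart from the others. The mean log2 CPM of cerebellar granule cell genes was 7.09 to 7.88 in the cerebellum libraries, against 2.61 to 3.70 in hippocampus and 2.60 to 3.49 in cortex. Purkinje cell genes lay at 7.20 to 7.58 in cerebellum, 3.31 to 4.41 in hippocampus and 3.16 to 3.89 in cortex. Cortical layer genes lay at 4.78 to 5.13 in cortex and 4.26 to 4.66 in hippocampus. Genes of dentate gyrus granule cells lay at 3.23 to 3.93 in 8 of the 9 hippocampus libraries, 2.16 to 2.78 in cortex and 1.43 to 2.20 in cerebellum. Genes of CA1 to CA3 pyramidal cells lay at 4.32 to 4.98 in the same 8 libraries and 3.60 to 3.98 in cortex. Hippocampus sham 2 stood apart, at 2.28 for dentate gyrus and 3.68 for pyramidal cell genes, within the cortex range. Genes of striatal medium spiny neurons lay at 6.61 in sham 2 and 6.42 in sham 1, against 2.83 to 3.61 in the other hippocampus libraries.

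In the hippocampus, 77 genes rose and 140 fell after bulbectomy among 13985 tested. The genes that rose with the smallest p were Lrrc8a, the essential subunit of the volume-regulated anion channel, Dpysl2, a collapsin response mediator of axon growth, and Nlgn3, a postsynaptic adhesion protein. They were joined by Tac2, which encodes the neurokinin B precursor, Chrnb4, a nicotinic acetylcholine receptor subunit, and Gng8, a G protein gamma subunit. Tac2, Chrnb4 and Gng8 are also known from the medial habenula, whose markers are treated below. The genes that fell with the smallest p included the clustered protocadherins Pcdhgc5, Pcdhga5 and Pcdhga4, the exchange factor Dock3, the prolyl endopeptidase-like enzyme Prepl and the potassium channel subunit Kcnf1. All 20 of the genes named for the smallest p had every bulbectomy library beyond every sham library.

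Lrrc8a (ENSMUSG00000007476, chromosome 2, 30237715 to 30263790) measured 49.5 ± 4.08 CPM after bulbectomy (SD, n = 4) and 10.7 ± 2.54 CPM after sham (n = 5), a log2 fold change of 2.19 ± 0.19 (SE; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 8.75e-05). Dpysl2 (ENSMUSG00000022048, chromosome 14, 66802864 to 66868688) measured 354 ± 79.7 CPM against 68.0 ± 16.3 CPM, with a log2 fold change of 2.38 ± 0.21 and the same adjusted p of 8.75e-05 by edgeR. Nlgn3 (ENSMUSG00000031302, chromosome X, 101299168 to 101325963) measured 58.7 ± 6.79 CPM against 18.8 ± 3.55 CPM, a log2 fold change of 1.63 ± 0.18 with an edgeR adjusted p of 0.000887. Tac2 (ENSMUSG00000025400, chromosome 10, 127724478 to 127731768) measured 23.4 ± 5.58 CPM against 5.39 ± 2.65 CPM, a log2 fold change of 2.15 ± 0.31 with an edgeR adjusted p of 0.00655. Log2 fold changes of the others that rose were 1.55 ± 0.20 for the heparan sulfate proteoglycan Sdc4, 1.77 ± 0.26 for the synapse organiser Cbln1, 1.30 ± 0.19 for Inafm2, 1.17 ± 0.17 for the retinal reductase Dhrs3, 2.63 ± 0.39 for Chrnb4 and 2.64 ± 0.39 for Gng8. Their adjusted p in edgeR was 0.00475 for Sdc4 and 0.00655 for the other 5.

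Pcdhgc5 (ENSMUSG00000102543, chromosome 18, 37819513 to 37841873) measured 25.4 ± 4.07 CPM after bulbectomy (SD, n = 4) and 68.8 ± 9.96 CPM after sham (n = 5), a log2 fold change of -1.44 ± 0.18 (SE; edgeR adjusted p = 0.00288). Gse1 (ENSMUSG00000031822, chromosome 8, 120228456 to 120581390) measured 6.91 ± 0.498 CPM against 27.9 ± 9.50 CPM, a log2 fold change of -2.00 ± 0.26 with an edgeR adjusted p of 0.00475. Prepl (ENSMUSG00000024127, chromosome 17, 85063470 to 85090241) measured 88.3 ± 18.3 CPM against 230.4 ± 38.6 CPM, a log2 fold change of -1.38 ± 0.19. Dock3 (ENSMUSG00000039716, chromosome 9, 106892825 to 107231909) measured 28.5 ± 3.14 CPM against 78.7 ± 19.97 CPM, a log2 fold change of -1.46 ± 0.20. Both had an edgeR adjusted p of 0.00522. The others that fell were Pcdhga5 at -2.59 ± 0.35, Pcdhga4 at -1.82 ± 0.27, Kcnf1 at -1.28 ± 0.18, the phosphatase regulatory subunit Ankrd52 at -1.48 ± 0.22, the pyridoxal kinase Pdxk at -1.17 ± 0.17 and the homeobox transcription factor Adnp at -4.70 ± 0.69. Their edgeR adjusted p lay between 0.00522 and 0.00660. Several of these genes share exons with others, so reads could have been split or dropped in counting. On the same strand as another gene lie 66.2% of the exon bases of Lrrc8a, 41.2% of Nlgn3, 39.6% of Pcdhgc5, 66.8% of Pcdhga4, 45.4% of Pcdhga5 and 82.1% of Adnp. On the opposite strand the shared part is 27.9% for Gse1, 10.8% for Prepl and 39.0% for Pdxk.

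**Figure D1:**
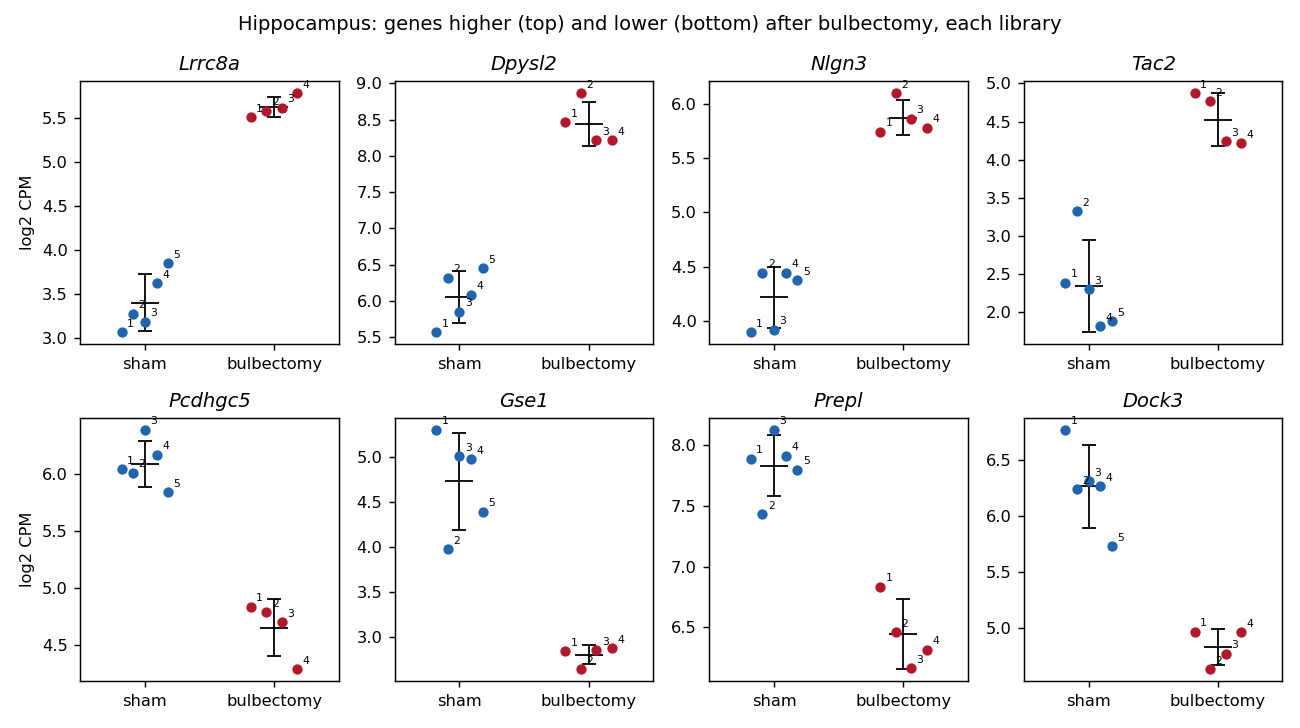
Log2 CPM of 4 genes that rose (top) and 4 that fell (bottom) in the hippocampus, with 1 point per library (numbers are replicate numbers), sham in blue and bulbectomy in red; bars give the mean and SD of 5 sham and 4 bulbectomy libraries. Every bulbectomy point lies beyond every sham point, for Lrrc8a and Dpysl2 with log2 fold changes of 2.19 and 2.38 and for Pcdhgc5 with -1.44.

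The 217 calls were made by edgeR's quasi-likelihood test at an adjusted p under 0.05; 2794 genes had an unadjusted p under 0.05, and 1373 genes (9.82%, where chance gives 1.59%) had groups that did not overlap. DESeq2 called 935, a fold threshold of 1.2 left 64, and removing a trend over exon length and GC content gave 440 (203 higher and 237 lower). Without bulbectomy 1, 2, 3 or 4 there were 50, 30, 69 and 34 calls, without sham 1, 2, 3, 4 or 5 there were 139, 477, 139, 72 and 299, and without sham 1 and 2 together 348.

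Markers of thalamus and habenula, tissue that borders the hippocampus, moved with the groups. Those of the choroid plexus did not, with 9 genes higher and 10 lower. Of 17 measured genes of thalamus and habenula, 15 were higher and 2 lower after bulbectomy, with a median log2 fold change of 0.72 (camera adjusted p = 6.06e-06; adjusted p = 0.957 with an estimated correlation). Among them 2 were called over all genes and 6 adjusted over the list alone. Gpr151, an orphan receptor of habenular neurons, rose from 0.346 ± 0.237 to 4.79 ± 3.03 CPM (log2 fold change 3.55 ± 0.54, edgeR adjusted p = 0.00660). The nuclear receptor Rora rose from 13.7 ± 3.09 to 44.6 ± 20.2 CPM (1.71 ± 0.29, edgeR adjusted p = 0.0137). Rora was no longer called without bulbectomy 4 (adjusted p = 0.0665) or sham 4 (0.0529), without sham 1 and 2 together (0.0657) or with all libraries in 1 fit (0.113). Tcf7l2, a thalamic transcription factor, measured 51.4 ± 14.1 against 13.3 ± 8.05 CPM (1.97 ± 0.49, edgeR adjusted p = 0.0773). The median was 0.47 without sham 1 and 2. The mean log2 CPM of the list was 4.06 ± 0.32 in the bulbectomy libraries and 2.93 ± 0.68 in the sham libraries.

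Genes of striatal medium spiny neurons were lower, 18 of 19 measured, with a median log2 fold change of -1.84 (camera adjusted p = 0.00335; adjusted p = 0.957 with an estimated correlation). None was called over all genes and 0 adjusted over the list alone. The phosphodiesterase Pde10a measured 6.46 ± 1.16 CPM after bulbectomy and 49.2 ± 57.6 CPM after sham. The level of the list was 6.42 and 6.61 log2 CPM in sham 1 and sham 2 but 2.83 to 3.27 in the other 3 sham libraries and 3.23 to 3.61 in the bulbectomy libraries. Without sham 1 its adjusted p was 0.107 and without sham 2 it was 0.252. Without both the median became 0.54, in the other direction (adjusted p = 0.00278).

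**Figure D2:**
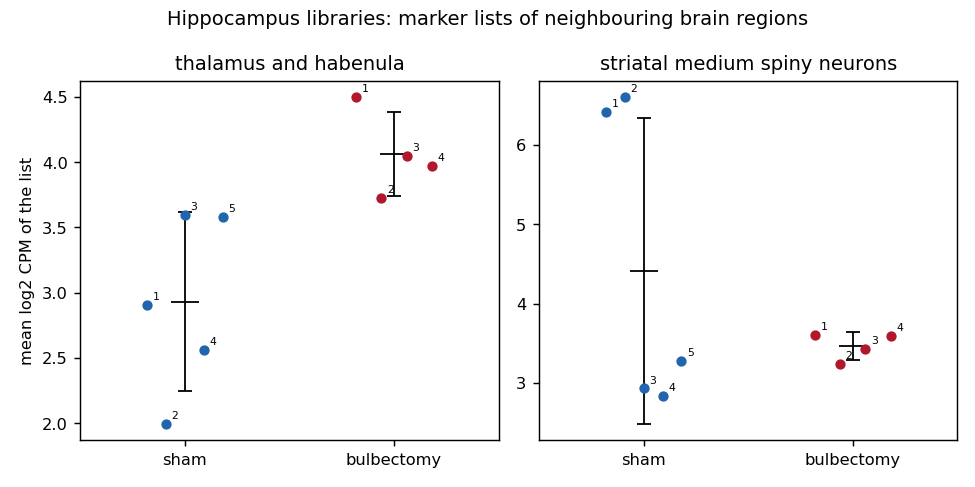
Mean log2 CPM of the thalamus and habenula list (left) and the striatal medium spiny neuron list (right) in each hippocampus library, sham in blue and bulbectomy in red, with replicate numbers; bars give the mean and SD of 5 sham and 4 bulbectomy libraries. Sham 1 and sham 2 stand at 6.42 and 6.61 on the right, above all the others.

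Of 20 measured glucocorticoid-induced genes 14 were higher and 6 lower in the hippocampus, with a median log2 fold change of 0.45 (camera adjusted p = 0.00242; adjusted p = 0.393 with an estimated correlation). This is the list that fry called (fry adjusted p = 0.0403), and its estimated correlation was 0.0141. The median was 0.22 without bulbectomy 3 and 0.29 without sham 3. Of the 20 genes 3 were called over all genes and 7 adjusted over the list alone. The called members were the lipid droplet protein Plin4, the glucocorticoid-induced leucine zipper Tsc22d3 and the NF-kappaB inhibitor Nfkbia. Plin4 measured 16.9 ± 1.75 against 7.18 ± 2.12 CPM, a log2 fold change of 1.2 ± 0.23. Tsc22d3 measured 42.2 ± 9.35 against 23.8 ± 3.06 CPM (0.82 ± 0.19) and Nfkbia 86.1 ± 15.1 against 47.6 ± 12.2 CPM (0.86 ± 0.20). Their edgeR adjusted p was 0.0266, 0.0470 and 0.0470, and Cdkn1a was not called (0.86 ± 0.25, 0.0852). Fkbp5, also a member of the list, was near unchanged at -0.020 and not called (-0.16 to 0.077 with a library left out). The call of Plin4 was lost without any of bulbectomy 1 to 4 or sham 3 (adjusted p 0.0521 to 0.103), that of Tsc22d3 without bulbectomy 1, 2 or 4 or sham 1, 3, 4 or 5 (0.0643 to 0.161), and that of Nfkbia without any of bulbectomy 1 to 4 or sham 1, 3, 4 or 5 (0.0585 to 0.143). All 3 were also lost with a fold threshold or 1 fit of all libraries, Nfkbia and Tsc22d3 with a non-robust fit, and Tsc22d3 with upper-quartile scaling, with no low-count filter or without sham 1 and 2 (adjusted p 0.0542 to 0.120 over these).

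Genes of the respiratory chain were higher as well. Of 35 nuclear-encoded members of oxidative phosphorylation 33 were higher (median log2 fold change 0.31, camera adjusted p = 7.51e-05; adjusted p = 0.957 with an estimated correlation), 1 being called over all genes and 2 adjusted over the list alone. The ATP synthase subunit gene Atp5g1 rose from 92.1 ± 19.8 to 169.6 ± 23.1 CPM (0.88 ± 0.18, edgeR adjusted p = 0.0332), a call lost without any of bulbectomy 1 to 4 or sham 4 (adjusted p 0.0698 to 0.117) and with a fold threshold (0.0879). Of 7 mitochondrial-encoded genes 6 were higher (median 0.48, camera adjusted p = 0.0317; adjusted p = 0.957 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone. mt-Nd1 measured 33223 ± 2654 against 21422 ± 4469 CPM (0.63 ± 0.20, edgeR adjusted p = 0.109). With the trend over exon length and GC content removed, the adjusted p was 0.0515 for the nuclear-encoded and 0.372 for the mitochondrial-encoded list, and the latter was also lost without bulbectomy 3 or sham 2, 3, 4 or 5 (0.0549 to 0.177). The median of the nuclear-encoded list was 0.17 without sham 1, without sham 4 or with the trend removed, and that of the mitochondrial-encoded list 0.28 without sham 3 and 0.80 without sham 1 and 2.

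None of the panel genes linked to Alzheimer's disease, depression or plasticity was called in the hippocampus by edgeR. Their adjusted p ran from 0.128 for the acetylcholinesterase gene Ache (log2 fold change 0.58 ± 0.20) to 0.975 for the immature neuron marker Dcx (0.036 ± 0.48). The amyloid precursor gene App measured 743.7 ± 50.3 CPM after bulbectomy and 929.7 ± 225.6 CPM after sham (-0.32 ± 0.19, adjusted p = 0.347). The tau gene Mapt measured 456 ± 89.8 and 352 ± 30.4 CPM (0.38 ± 0.16, adjusted p = 0.223). Values for the astrocyte filament gene Gfap were 2808 ± 1381 and 1647 ± 617 CPM (0.77 ± 0.33, adjusted p = 0.225), and for the neurotrophin gene Bdnf 7.91 ± 1.79 and 6.42 ± 2.28 CPM (0.30 ± 0.30, adjusted p = 0.593). With the length and GC trend removed App was -0.010 and Bdnf 0.55, and Bdnf was 0.12 to 0.18 without bulbectomy 2, sham 2, sham 3 or sham 1 and 2 together. Gfap was 0.46 with voom and Mapt 0.25 without bulbectomy 4.

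In the cortex 3 genes rose and 0 fell after bulbectomy among 14847 tested. They were Ecel1, a neuronal endopeptidase of the endothelin-converting enzyme family, Ly6g6e, a lymphocyte antigen family member, and Tmem40, a transmembrane protein. Ecel1 (ENSMUSG00000026247, chromosome 1, 87147655 to 87156521) measured 63.3 ± 29.3 CPM after bulbectomy (SD, n = 3) and 7.71 ± 2.03 CPM after sham (n = 5), a log2 fold change of 3.03 ± 0.30 (SE; edgeR adjusted p = 0.00374). Ly6g6e (ENSMUSG00000013766, chromosome 17, 35076902 to 35078804) measured 6.44 ± 2.93 against 0.611 ± 0.288 CPM (3.37 ± 0.41), with 18% of its exon bases in a gene on the opposite strand. Tmem40 (ENSMUSG00000059900, chromosome 6, 115729131 to 115762410) measured 15.6 ± 8.67 against 1.97 ± 0.365 CPM (2.99 ± 0.37). Ly6g6e and Tmem40 had an edgeR adjusted p of 0.0123. The next by p, the neuropeptide gene Cartpt (74.5 ± 45.3 against 18.2 ± 3.26 CPM, 2.03 ± 0.30) and the transthyretin gene Ttr (16.7 ± 5.96 against 2.98 ± 1.45 CPM, 2.49 ± 0.38), were not called, each with an adjusted p of 0.0603. All 3 bulbectomy libraries lay above every sham library for these 5 genes; over all genes 3.64% had groups that did not overlap, where chance gives 3.57%.

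The cortex count came from edgeR's quasi-likelihood test, with 877 genes at an unadjusted p under 0.05. DESeq2 called 39, voom with sample weights 252, RLE scaling 7, no low-count filter 24, the trend removed 7 and 1 fit of all libraries 5. Without bulbectomy 1 the count was 573 (304 higher and 269 lower) and without bulbectomy 4 it was 10. It was 4 without sham 3 or sham 4, but without bulbectomy 2 or sham 1, 2 or 5 Ecel1 alone was left (adjusted p of Ly6g6e and Tmem40 0.0521 to 0.0963).

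Among the gene lists of the cortex, neuropeptides and interferon response genes had the smallest camera p at the preset correlation. Of 21 neuropeptide and neurotrophic factor genes 19 were higher, with a median log2 fold change of 0.46 (camera adjusted p = 5.23e-10; adjusted p = 0.122 with an estimated correlation). Over all genes 0 were called and 7 adjusted over the list alone. The smallest p were those of Npy (171 ± 88.3 against 62.8 ± 14.7 CPM, 1.44 ± 0.30, edgeR adjusted p = 0.333), Sst (297 ± 87.0 against 165.5 ± 23.9 CPM, 0.84 ± 0.20, 0.384), Cort (1.198 ± 0.29, 0.384) and Penk (0.89 ± 0.23, 0.501). Of 27 interferon response genes 25 were lower (median -0.73, camera adjusted p = 1.26e-13; adjusted p = 0.287 with an estimated correlation), with 0 called and 2 adjusted over the list alone. Ifi44 measured 1.10 ± 0.321 against 3.25 ± 0.736 CPM (-1.53 ± 0.36, edgeR adjusted p = 0.384). The antiviral GTPase gene Mx1 measured 0.2495 ± 0.0532 against 1.23 ± 0.476 CPM (-2.27 ± 0.56, edgeR adjusted p = 0.384). In the cortex bulbectomy libraries 3 reads make 0.217 to 0.253 CPM, so the value of Mx1 there rests on few reads.

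Glucocorticoid-induced genes were higher in the cortex too, 17 of 20, with a median log2 fold change of 0.32 (camera adjusted p = 8.69e-05; adjusted p = 0.268 with an estimated correlation) and 0 called and 2 adjusted over the list alone. Without bulbectomy 1 the adjusted p was 0.0723. Tsc22d3 measured 43.1 ± 8.15 against 22.6 ± 4.69 CPM (0.93 ± 0.21, edgeR adjusted p = 0.376). Genes of striatal medium spiny neurons (14 of 18 higher, median 0.43) and hypothalamus (5 of 5 higher, 0.60) each had a camera adjusted p of 3.73e-05, and an adjusted p = 0.508 and 0.374 with an estimated correlation. They had 0 called, and 3 and 1 adjusted over the list alone. The mean log2 CPM of the striatal list was 3.55 to 4.02 in the bulbectomy libraries and 3.07 to 3.21 in sham 1 to 4, but 3.93 in sham 5. Penk and Tac1 stand in both the striatal and the neuropeptide list, and Cartpt leads the hypothalamus list, whose median was 0.36 without bulbectomy 4. Genes of meningeal and perivascular fibroblasts (14 of 18 higher, median 0.16, camera adjusted p = 0.00438; adjusted p = 0.570 with an estimated correlation) had 0 called and 2 adjusted over the list alone, led by Fmod (0.80 ± 0.19) and Ptgds (0.74 ± 0.19). That list was lost without bulbectomy 1 (0.407), and its median was 0.29 without bulbectomy 2, 0.11 without sham 2 and 0.25 with the trend removed. Disease-associated microglia genes (13 of 20 higher, median 0.20, camera adjusted p = 0.0168; adjusted p = 0.629 with an estimated correlation) had 0 called and 1 adjusted over the list alone, led by the lysosomal gene Cd68 (29.4 ± 1.68 against 17.0 ± 1.49 CPM, 0.79 ± 0.17, edgeR adjusted p = 0.333). They were lost without bulbectomy 1 or 4 or sham 1 or 3 (adjusted p 0.0505 to 0.536) and with the trend removed (0.105), and the median turned to -0.047 without bulbectomy 4.

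Respiratory and ribosomal genes of the cortex were higher by small amounts. Nuclear-encoded oxidative phosphorylation genes were higher in 32 of 35 cases (median 0.17, camera adjusted p = 0.000897) and mitochondrial-encoded genes in 7 of 7 (0.55, 0.000131). With an estimated correlation their adjusted p = 0.735 and 0.629. Ribosomal protein genes were higher in 36 of 39 cases (0.22, camera adjusted p = 0.00119) and oxidative stress response genes in 21 of 26 (0.22, 0.000521). With an estimated correlation their adjusted p = 0.735 and 0.508. In each of these 4 lists 0 members were called and 0 adjusted over the list alone. The oxidative phosphorylation list was lost without bulbectomy 2 or 4 or sham 5 (adjusted p 0.0507 to 0.391) and with the trend removed (0.0912), and its median ran from 0.067 without bulbectomy 4 to 0.39 without bulbectomy 1. The mitochondrial-encoded median was 0.26 without bulbectomy 2 and 0.35 without sham 2, and that of oxidative stress genes 0.35 without bulbectomy 1. The ribosomal list was lost without sham 5 (0.110) or with the trend removed (0.175), and its median was -0.076 without bulbectomy 4 (0.183) and 0.45 without bulbectomy 1. No panel gene was called in the cortex, where adjusted p ran from 0.0603 for Ttr to 0.997 for Dcx. This depended on the method: of 19 alternatives Ttr was called in 8, Npy in 3, Sst in 2 and Ache in 2.

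In the cerebellum 2 genes rose and 0 fell after bulbectomy among 15295 tested. Tpm3-rs7, a tropomyosin-related sequence (ENSMUSG00000058126, chromosome 14, 113314608 to 113316754), measured 37.8 ± 20.5 CPM after bulbectomy (SD, n = 2) and 0.619 ± 0.352 CPM after sham (n = 5), a log2 fold change of 5.91 ± 0.53 (SE; edgeR adjusted p = 0.0473). The other was the predicted gene Gm14719, named here only after its values were seen, at 5.76 ± 0.0151 against 0.0299 ± 0.0422 CPM with the same adjusted p of 0.0473. Values of the next genes by p, none of them called, were 2.74 ± 0.47 for the microRNA host gene Mir124a-1hg, 1.60 ± 0.29 for Lrrc8a, 1.66 ± 0.32 for Leng8 and 1.04 ± 0.20 for Bmp1 on the log2 scale. Lrrc8a measured 57.9 ± 11.2 against 19.1 ± 5.66 CPM.

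**Figure D3:**
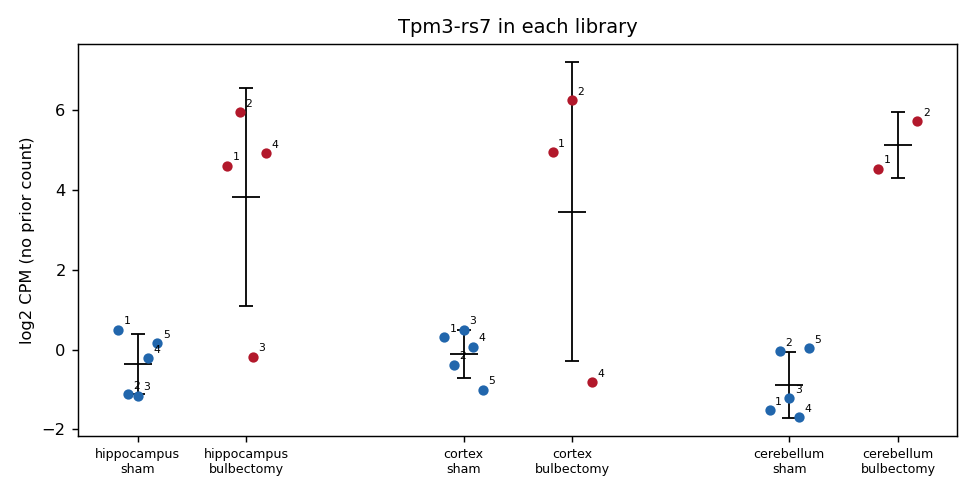
Tpm3-rs7 in each of the 24 libraries as log2 CPM without a prior count, sham in blue and bulbectomy in red, with replicate numbers; bars give the mean and SD of each group. The bulbectomy libraries lie at 23.2 to 75.8 CPM except hippocampus 3 at 0.881 and cortex 4 at 0.570 CPM, which lie among the sham libraries.

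The cerebellum count came from edgeR's quasi-likelihood test, with 454 genes at an unadjusted p under 0.05 and 10.9% of genes with groups that did not overlap, where chance gives 9.52%. DESeq2 called 11 and voom with sample weights 67. It was 36 without sham 1, 61 without sham 1 and 2 together, and 0 without any other single library, with an adjusted p of Tpm3-rs7 of 0.101 to 0.780. A fit with 1 bulbectomy library left assumes that it varies like the sham group.

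Of the gene lists, mitochondrial-encoded genes were higher in 7 of 7 cases in the cerebellum, with a median log2 fold change of 0.79 (camera adjusted p = 3.28e-09; adjusted p = 0.631 with an estimated correlation). Glucocorticoid-induced genes were higher in 16 of 20 cases (median 0.32, camera adjusted p = 2.25e-05; adjusted p = 0.172 with an estimated correlation), led by the clock gene Per1 (124.9 ± 4.24 against 79.1 ± 9.60 CPM, 0.66 ± 0.18) and the stress-response gene Ddit4 (78.3 ± 8.48 against 48.7 ± 9.11 CPM, 0.69 ± 0.22). Interferon response genes were higher in 19 of 26 (0.18, camera adjusted p = 0.0466) and fibroblast genes lower in 14 of 18 (-0.23, 0.0466); both had an adjusted p = 0.952 with an estimated correlation. In each of the 4 lists 0 members were called and 0 adjusted over the list alone. Over the alternatives the median of the glucocorticoid list ran from 0.25 to 0.51. The interferon list was lost without bulbectomy 1, sham 1 or sham 3 (adjusted p 0.395 to 0.417), without sham 1 and 2 together (0.538), with no low-count filter (0.123) or with the trend removed (0.0899). With 1 library left out its median ran from 0.015 (sham 1) to 0.54 (sham 4). With a sham library left out, the fibroblast list was lost without sham 2, 3 or 5 (camera adjusted p 0.112 to 0.216). Fits without bulbectomy 1 or 2 leave 1 bulbectomy library, so only the median of this list is given for them and its call cannot be judged there. The median of the fibroblast list was -0.40 without bulbectomy 1, -0.26 without bulbectomy 2, -0.15 without sham 5 and -0.097 with the replicate block.

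Compared between tissues, most genes called in the hippocampus had the same sign elsewhere. Of 211 of them tested in the cortex, 208 (98.6%) had the same sign, 58 of these at an unadjusted p under 0.05, against 72.4% same signs over all genes. In the cerebellum it was 200 of 212 (94.3%), 62 at an unadjusted p under 0.05, against 68.4% over all genes. Fold changes correlated across genes, which are not independent replicates, at Pearson's r = 0.522 between hippocampus and cortex, 0.529 between hippocampus and cerebellum and 0.458 between cortex and cerebellum. Without cortex bulbectomy 1 the first and the last were 0.658 and 0.587, and 102 of 212 hippocampus genes were called in the cortex. The tissues have separate libraries, but those of the same number and treatment deviated together from their groups, with a correlation above 0.1 in 18 of 22 pairs, and may come from the same animals.

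Values with no operation were therefore taken, after the results were seen, from the sham libraries, split 2 against 3 by the same numbers in every tissue. On the measure used for them, differences of mean log2 CPM, Pearson's r across genes of bulbectomy against sham was 0.593 between hippocampus and cortex, 0.536 between hippocampus and cerebellum and 0.544 between cortex and cerebellum. Over the 10 sham splits it was 0.114 to 0.592, 0.0759 to 0.708 and -0.129 to 0.602. As many top genes of each split in the hippocampus as there were calls had the same sign in the cortex in 37.4% to 96.8% of cases and in the cerebellum in 48.7% to 100%. The observed share of 94.3% in the cerebellum was reached by 2 of these splits and that of 98.6% in the cortex by 0. Animals shared by the tissues weigh more in these small sham groups than in the real comparison. The covariance of log2 differences was 0.115, 0.116 and 0.0912 for the 3 pairs of tissues, where sharing of animals alone, estimated from the sham splits as if numbers mark animals and both groups vary alike, would give 0.0311, 0.0796 and 0.0372.

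A score of the hippocampus genes, the mean log2 CPM of those that rose minus that of those that fell, was taken after the calls were seen. Set to 0 at the sham mean of each tissue, it was 0.036, 1.97 and 2.10 in cortex bulbectomy 1, 2 and 4 and -0.25 to 0.27 in the cortex sham libraries (two-sided exact permutation p = 0.0714 over 56 splits; smallest possible 0.0179). In the cerebellum it was 1.44 and 1.40 after bulbectomy and -0.52 to 0.51 after sham (two-sided exact permutation p = 0.0476, the smallest that 21 splits allow). These p take the libraries as independent of those of the hippocampus, where the genes were chosen.

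**Figure D4:**
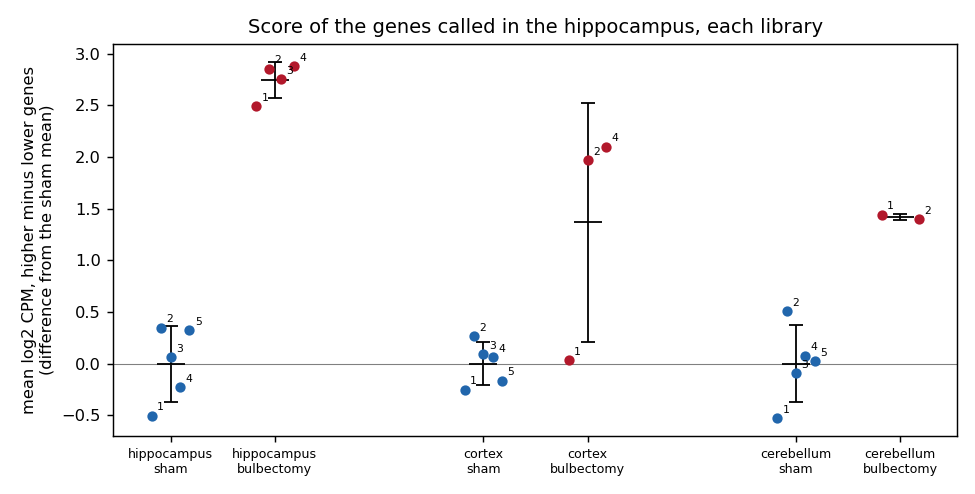
Score of the genes called in the hippocampus (mean log2 CPM of those that rose minus those that fell, difference from the sham mean of the tissue) in each library, sham in blue and bulbectomy in red, with replicate numbers; bars give the mean and SD of each group. In the hippocampus the genes were chosen for this difference; in the cortex bulbectomy 2 and 4 lie at 1.97 and 2.10 and bulbectomy 1 at 0.036, among the sham libraries.

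Direct tests of a difference in effect called 0 of 16564 genes for each pair of tissues by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 466 genes for hippocampus against cortex, 511 for hippocampus against cerebellum and 276 for cortex against cerebellum. In simulated counts these tests called 6.8%, 6.8% and 1.5% of 2-fold differences. Voom with a correlation between libraries of the same number and treatment called 2, 4 and 0. The smallest adjusted p over the pairs was 0.0709, for a predicted gene between hippocampus and cerebellum. Between hippocampus and cortex it was 0.159, for Ecel1 (difference of log2 fold changes -3.23 ± 0.57), with Chrnb4 at 4.03 ± 0.80 (0.190). For hippocampus against cortex 1 gene was called without hippocampus sham 4 or cerebellum sham 1. For hippocampus against cerebellum 2 were called without hippocampus bulbectomy 4 and 1 without cortex sham 1, 3 or 4 or cerebellum sham 2.

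Called genes were shared between tissues only for Tpm3-rs7, which rose in hippocampus (29.5 ± 25.2 against 0.856 ± 0.424 CPM, log2 fold change 5.19 ± 0.99, edgeR adjusted p = 0.0470) and cerebellum. This overlap of 1 gene compares with 0.00536 for independent lists (Fisher's exact test, adjusted p = 0.0321, but 0.116 for the same gene with calls at an adjusted p under 0.1). Hippocampus and cortex shared 0 calls in either direction, where independent lists would share 0.0154 of those that rose. With DESeq2 calls they shared 10 genes that rose (adjusted p = 2.78e-11), Lrrc8a and Dpysl2 among them, and 4 that fell (2.42e-05). With cortex calls made without bulbectomy 1, a library left out of this overlap after its score was seen, they shared 28 and 74. Part of these overlaps may come from animals shared by the tissues.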

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

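No test in this part was chosen after its result was seen. A library stood far from the rest of its group, by Dixon's critical value for the gap to the nearest other library, in 20 of the 289 sets of 4 or 5 libraries examined, where chance gives about 1 in 20, and 19 of them are given below. No biological explanation was tested for the values below.

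In the hippocampus, sham 4 held 138963332 assigned reads against 3255661 to 9608811 in the other sham libraries. Sham 1 held Tsc22d3 at 4.22 log2 CPM (others 4.59 to 4.71) and mt-Nd4 at 13.10 (11.83 to 12.06). Sham 2 had dentate gyrus granule cell genes at a mean log2 CPM of 2.28, against 3.46 to 3.93 in the other sham libraries. Bulbectomy 2 had lower values than the other bulbectomy libraries for Gse1 (2.64 against 2.84 to 2.87 log2 CPM) and Tcf7l2 (4.93 against 5.82 to 5.94). Bulbectomy 3 had Htr2a at -1.58 log2 CPM (others 0.47 to 0.78) and genes of CA1 to CA3 pyramidal cells at 4.73 (4.90 to 4.93).

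In the cortex, sham 3 held Atp5g1 at 6.48 log2 CPM (others 6.18 to 6.26). Sham 5 held Rpl37 at 7.95 log2 CPM (8.43 to 8.63) and genes of striatal medium spiny neurons at a mean of 3.93 (3.07 to 3.21).

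In the cerebellum, 74.77% of the assigned reads of sham 2 fell in protein-coding genes, against 94.06% to 97.76% in the other sham libraries, and 9.22% of its reads overlapped no gene, against 2.79% to 3.86%. The same library had genes of the olfactory bulb and anterior olfactory areas at a mean log2 CPM of 1.43 (others 0.95 to 1.08). Sham 1 held Bace1 at 6.33 log2 CPM (5.30 to 5.38), Clu at 10.001 (10.69 to 10.87) and Nr3c1 at 6.67 (3.85 to 4.63). Sham 3 held Ifih1 at 0.88 log2 CPM (1.69 to 1.97) and sham 5 held mt-Nd1 at 14.19 (13.38 to 13.61).

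The share of reads overlapping no gene, which no comparison used, was above every sham library of the tissue in hippocampus bulbectomy 3 (4.24%) and 4 (5.44%), where sham libraries held 2.62% to 3.96%, and in cortex bulbectomy 4 (5.13%), where they held 2.84% to 3.37%.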

How the results depend on the processing

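Removing the length and GC trend, thinning hippocampus sham 4, leaving out sham 1 and 2 together, and remaking the overlap without cortex bulbectomy 1 were chosen after the data were seen. No gene called in the hippocampus, cortex or cerebellum changed sign in an alternative that tested it. Of the 26 named genes called in the hippocampus 20 stayed called in every alternative. Over the 572 results of these genes 526 stayed called and 46 did not. In the cortex 49 of 57 and in the cerebellum 12 of 19 stayed called. The 20 hippocampus genes are those named for the smallest p, so they do not stand for all calls. Of all 217, 49, 30, 65 and 32 stayed called without bulbectomy 1, 2, 3 and 4. With all libraries in 1 fit 120 of them stayed called. Named genes that were not called became called in 26 of 791 results in the hippocampus, 57 of 1177 in the cortex and 19 of 740 in the cerebellum. Among named genes that were not called, 27 changed sign in some alternative, with a smallest adjusted p of 0.413 there. The cause of these changes was not tested, except that leaving out libraries lowers the number of samples. Depth was a limit mainly in hippocampus sham 1, with 3255661 assigned reads, and for genes with few reads, such as Mx1 in the cortex bulbectomy libraries. Thinning hippocampus sham 4 gave 202 calls, 198 of them among the 217.

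Of the 217 hippocampus calls, DESeq2 kept all 217 and called 935, a fold threshold of 1.2 left 64, removing the trend gave 440 and leaving out sham 1 and 2 gave 348. Single libraries left out gave 30 (bulbectomy 2) to 477 (sham 2). Removing the trend raised the share called higher from 77 of 217 to 203 of 440. The 3 cortex calls became 39 with DESeq2, 252 with voom, 7 with RLE scaling, 24 with no low-count filter, 7 with the trend removed and 5 with all libraries in 1 fit. They became 1 (bulbectomy 2) to 573 (bulbectomy 1) with a library left out. The 2 cerebellum calls became 11 with DESeq2, 67 with voom and 61 without sham 1 and 2, and 0 (bulbectomy 1) to 36 (sham 1) with a library left out.

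The number of called gene lists fell to 0 in hippocampus, cortex and cerebellum with an estimated correlation, and fry called 1, 0 and 0. The 5 hippocampus lists became 10 with no low-count filter and 10 without sham 1 and 2. With a library left out the counts were 4 to 10 in the hippocampus, 10 to 15 in the cortex and 2 to 7 in the cerebellum. Genes called for a difference in effect, 0 for each pair, became 2 for hippocampus against cortex and 4 for hippocampus against cerebellum with voom and an estimated correlation between libraries of 1 number. With a library left out they were 0 to 1 and 0 to 2. Shared calls of hippocampus and cortex went from 0 to 1 at an adjusted p under 0.1, to 10 with DESeq2 and 28 without cortex bulbectomy 1 for genes that rose, and to 4 and 74 for genes that fell. With DESeq2, hippocampus and cerebellum shared 4 that rose and 3 that fell, and cortex and cerebellum 2 and 2.

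The replicate block changed the calls to 76 in the hippocampus (62 of them among the 217), 13 in the cortex and 0 in the cerebellum, and the lists in the cerebellum from 4 to 12. The numbers were not taken to pair bulbectomy with sham libraries: of 9 same-numbered pairs 4 had deviations correlated above 0.1 (-0.36 to 0.37), and 2 libraries correlated best with their own number. Both of these are in the cerebellum (0.371 and 0.283), where there are 2 pairs, so a pairing there stays open. With the block the adjusted p was 0.0659 for Gpr151, 0.0682 for Plin4 and Atp5g1, 0.101 for Tsc22d3 and 0.0842 for Nfkbia in the hippocampus and 0.0779 for Tpm3-rs7 in the cerebellum. It was 0.0858 for the hippocampus mitochondrial-encoded, 0.0921 for the cortex disease-associated microglia and 0.537 for the cerebellum fibroblast list, and the median of the cerebellum interferon list was 0.98. With the block, values that changed sign were Aif1 at -0.030 and Dcx at -0.20 in the hippocampus, Gfap at -0.036, Fos at 0.23 and Dcx at -0.014 in the cortex, and Apoe at 0.23, Trem2 at 0.11, Clu at 0.26, Gfap at 0.19, Fos at 0.63 and Ttr at -1.72 in the cerebellum.

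Other changes of sign, all on the log2 scale, were as follows. In the hippocampus, voom gave Trem2 0.023, Fkbp5 0.073 and Dcx -0.20, and upper-quartile scaling Dcx -0.013. Removing the trend gave Apoe -0.26 and Fkbp5 0.12. The fit without sham 1 and 2 gave Trem2 0.17, Fkbp5 0.033 and the striatal list 0.54. That list is the only result that changed sign and was called in the other direction (adjusted p = 0.00278). In the cortex, voom gave App 0.046, Mapt -0.018, Gfap -0.030, Crh -0.041, Arc -0.072 and Dcx -0.068, the trend removed gave App 0.031, and 1 fit of all libraries Aif1 0.0089. Dcx was -0.0099 with DESeq2, -0.0087 with RLE scaling, -0.0091 with upper-quartile scaling, -0.0095 with no low-count filter and -0.021 with a mean of at least 1 CPM. In the cerebellum, voom gave Bace1 0.091, Bdnf 0.34 and Arc -0.0048, upper-quartile scaling Clu 0.0054, DESeq2 Arc -0.010 and RLE scaling Arc -0.012. Removing the trend gave Bdnf 0.14 and Arc -0.11. The fit without sham 1 and 2 gave Bace1 0.11, Bdnf 0.39 and Arc -0.12.

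With a library left out, the ranges of results that changed sign were, in the hippocampus, Apoe -0.067 to 0.13, Trem2 -0.39 to 0.12, Aif1 -0.47 to 0.52, Npy -0.21 to 1.49, Fkbp5 -0.16 to 0.077 and Dcx -0.25 to 0.33. In the cortex they were App -0.27 to 0.080, Mapt -0.16 to 0.24, Gfap -0.16 to 0.29, Aif1 -0.16 to 0.083, Crh -0.13 to 0.44, Nr3c1 -0.57 to 0.013, Arc -0.34 to 0.70, Fos -0.88 to 0.14, Dcx -0.45 to 0.21, the ribosomal list -0.076 to 0.45 and the disease-associated microglia list -0.047 to 0.27. In the cerebellum they were Bace1 -0.22 to 0.11, Apoe -0.20 to 0.048, Trem2 -0.44 to 0.036, Clu -0.14 to 0.054, Aif1 -0.43 to 0.016, Bdnf -1.0 to 0.53, Npy -0.039 to 0.60, Sst -0.86 to 0.16, Arc -0.090 to 0.064 and Ttr -5.10 to 1.28.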

Other observations

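The length and GC trend, the pseudogene comparison, the sham splits by number and the level of Tpm3-rs7 in cortex bulbectomy 1 were chosen only after results were seen. So were the correlation of thalamus and habenula genes, the count of libraries with Tpm3-rs7, the protocadherin groups and the genes of the next 2 paragraphs. The protocadherin prediction was written before its own comparison, but after the hippocampus calls, Pcdhg genes among them, were seen. The splits of the libraries were written beforehand.

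Clustered protocadherins, cell-surface proteins whose combinations give neurons an identity, were grouped after the hippocampus calls were seen and not tested as a family. Of 21 Pcdhg genes tested 10 were called lower and 0 higher (median log2 fold change -1.28), of 4 Pcdha genes 2 were called lower (median -1.71), and of 17 Pcdhb genes none was called by edgeR, 7 being lower at an unadjusted p under 0.05 (median -0.83). The Pcdha and Pcdhg genes together had a median of -1.28 with TMM, -1.30 with RLE and -1.34 with upper-quartile scaling. In the cortex the medians were -0.94, -0.40 and -0.46 for Pcdha, Pcdhb and Pcdhg, and in the cerebellum -1.60, -0.89 and -0.56, with 0 genes called in either by edgeR. Members of a cluster share exons, so counts of single members are uncertain.

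Other genes called in the hippocampus by edgeR's quasi-likelihood test include Nfia, which rose by a log2 fold change of 1.25 ± 0.20 (SE; 33.5 ± 8.59 CPM after bulbectomy, n = 4, and 14.0 ± 2.24 after sham, n = 5; adjusted p = 0.0115), Sox9 by 1.17 ± 0.22 (adjusted p = 0.0239), Zbtb20 by 1.24 ± 0.27 (0.0384) and Nfib by 0.97 ± 0.23 (0.0489). The calcium pump genes Atp2b3 and Atp2b4 changed by -1.44 ± 0.26 (adjusted p = 0.0180) and -0.98 ± 0.18 (0.0244), the calcium channel Cacna1c by -0.96 ± 0.20 (0.0338), the adenylyl cyclases Adcy9 and Adcy3 by -1.27 ± 0.22 (0.0137) and -0.83 ± 0.17 (0.0354), and the phosphodiesterase Pde4d by -1.60 ± 0.28 (0.0137). The sodium leak channel Nalcn changed by -1.11 ± 0.25 (0.0423) and the extracellular glycoprotein Reln by -0.84 ± 0.18 (0.0364). These are single genes picked from the 217 calls after they were seen, and no group of them was tested.

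The genes called in the hippocampus shifted the same way in both cerebellum bulbectomy libraries and in cortex bulbectomy 2 and 4, but cortex bulbectomy 1 lay among the sham libraries. Fold changes were more negative for longer genes (Spearman's rho across genes -0.330 in hippocampus, -0.258 in cortex and -0.258 in cerebellum). They were more positive for genes of higher GC content (0.282, 0.216 and 0.283). Without cortex bulbectomy 1 the cortex values were -0.366 for length and 0.345 for GC content, so both trends were stronger without the library that lacked the shift. With the trend over exon length and GC content removed, 201 of the 217 genes were still called in the same direction. This argues against that trend as the whole cause. A loss of reads far from the 3' end was predicted to spare the single-exon Pcdhb genes. Their median was -0.83, against -1.28 for Pcdha and Pcdhg, so they were not spared but fell less. A long single exon can lose reads in this way too, so the comparison cannot decide and this cause stays open. Genes called lower had a median exon length of 7308 bases, those called higher 4733.5 and all genes tested 4420. A candidate explanation is that libraries of the same number vary together across tissues: with sham libraries alone split by number, 2 of 10 splits gave their top hippocampus genes the same sign in the cerebellum at least as often as the called genes (up to 100% against 94.3%), and 0 of 10 in the cortex (up to 96.8% against 98.6%). Shared animals weigh more in these small groups than in the real comparison, so these shares are not like for like. The covariance that sharing alone would give, scaled for this, was 0.0796 for hippocampus and cerebellum, where 0.116 was observed. For hippocampus and cortex it was 0.0311, where 0.115 was observed. Sharing as estimated from the sham splits therefore falls short of the observed values. An exchange of cortex bulbectomy 1 with a sham library is argued against by its 30.8 CPM of Tpm3-rs7, where the highest of 15 sham libraries had 1.41. Over 398 pseudogenes it and the libraries labelled bulbectomy 1 were closest to each other in 3 of 4 comparisons. Cerebellum bulbectomy 1 lay closer to cortex bulbectomy 2 (0.359 against 0.335), so pseudogenes leave another bulbectomy animal open. Every other bulbectomy library carried the shift. Their scores were 1.97 and 2.10 in cortex, 1.44 and 1.40 in cerebellum and 2.49 to 2.88 in hippocampus, where the genes were chosen. These values argue against another bulbectomy animal measured here as the cause of the missing shift. An animal not measured here, an unlabelled batch and a response that 1 cortex sample lacked stay open, untested.

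Thalamus and habenula genes were higher in the bulbectomy hippocampus, and Tac2, Chrnb4, Gng8 and Gpr151, which are known from the medial habenula, were among the called genes. A candidate explanation is more bordering tissue in those dissections, since the list members varied together between libraries of 1 group, with an estimated correlation of 0.4995 where the median of 50 lists was 0.123; 19 lists reached 0.25, so this is not special to the list. Its abundant members Calb2, Tcf7l2 and Rora measured 118.5, 51.4 and 44.6 CPM after bulbectomy and 64.3, 13.3 and 13.7 CPM after sham. Of its 17 measured genes 16 averaged at least 1 CPM in the sham hippocampus and 4 stand in another list. A change of expression within the hippocampus after bulbectomy stays open and was not tested.

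Tpm3-rs7 and Gm14719 were high in 7 bulbectomy libraries, but 2 of the 9 bulbectomy libraries, hippocampus 3 (0.881 CPM) and cortex 4 (0.570 CPM), lay within the sham range for Tpm3-rs7, and Gm14719 was 0 in the same 2. A hypothesis is therefore a sequence or copy difference carried by some animals, which these counts cannot show; an effect of bulbectomy in part of the animals stays open, untested. Hippocampus bulbectomy 4 had 30.3 CPM of Tpm3-rs7 where cortex bulbectomy 4 had 0.570, so under this hypothesis libraries numbered 4 may not come from 1 animal. Over pseudogenes, cortex bulbectomy 4 correlated with hippocampus bulbectomy 4 and 3 at 0.318 and 0.298, and the closest library carried the same number in 41 of 44 comparisons.

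Other splits of the same libraries showed how far chance can be excluded. In the hippocampus 1 of 100 splits drawn from 126, the real one, gave 217 genes. The highest other gave 215 and set sham 1, 3, 4 and 5 against the rest. This share argues against chance for the count only if the libraries are independent, and it cannot tell the operation from a batch. Of the 5 splits that move 1 sham library to the bulbectomy group 3 were drawn, and the other 2 were not run. In the cortex 3 of 56 splits gave at least the 3 genes found, with 46 in the highest other, and chance cannot be excluded. The counts of gene lists, 5 in the hippocampus and 11 in the cortex, were reached by 94 of 100 splits (highest other 26) and by 28 of 56 (highest other 23), so chance cannot be excluded for either. For the difference in effect between hippocampus and cortex the real count was 0, which each of the 60 splits drawn from 7056 reaches whatever it gives (highest other 5), so these splits say nothing about chance there. In the cerebellum the 2 genes and 4 lists found were reached by 2 of 21 splits and 20 of 21 (highest other 1121 and 21), and chance cannot be excluded for either. Setting bulbectomy 1 and sham 1 against the rest gave the 1121 genes, which points to a structure of the samples other than the operation.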
